A study of Homo sapiens with 480 samples.

How the data were processed

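Hypersensitive regions were profiled by iDNase-seq, a multiplexed DNase-seq in which nuclei are barcoded first by an adaptor and then by a PCR index. Per the labels' protocols, white blood cells were crosslinked in 2 steps, the cells were digested with DNase I at 0.1 U/µl for 5 minutes at 37 °C, and barcoded adaptors were added with terminal transferase and T4 DNA ligase for 60 minutes. T cells were placed in adaptor wells 1 to 15, B cells in 16 to 30, NK cells in 31 to 45 and monocytes in 46 to 61. The nuclei were pooled and redistributed at 20 per well of a 96-well plate, amplified for 12 and then 16 cycles, and selected at 200 to 500 bp.

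The deposited matrix holds whole-number counts per region and cell, per the file headers, and was used as raw counts with no normalization. Bowtie2 and the hg18 build are named per the submitters' processing notes. The Bowtie2 version, the caller that defined the regions, the rule that kept cells and any removal of PCR duplicates are not given in the sources used here. Duplicates left in the counts would make the intervals too narrow. The deposited region list was matched to the matrix by row number: width and count had a Spearman correlation of 0.826 with the rows matched and 0.094 with the rows shifted by 1. Of the regions, 99.9% started on a multiple of 100 and ended at 99, so starts and ends were read as counted from 0 with both ends included, and are given counted from 1. On chromosome 19 the regions reached position 63789900, and 665 of them ended beyond the last gene of the GRCh38 gene table there; that table is of another build and was not used for positions or names. Gene names, cell type markers and distances to promoters were therefore not analysed here, and the marker lists fixed in advance could not be applied. The list of 480 barcode pairs (48 first barcodes of 6 bases and 10 second barcodes of 8) carries no library names and was only counted.

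All cells were treated as 1 sample because no map from cells to libraries or adaptor wells was used here. No test between groups was made, no p-value was computed, and cells were not taken as replicates. Only autosomes were analysed beyond the totals per cell. Cells were grouped on the odd-numbered autosomes (109138 regions, 4978888 counts) using the 56749 regions with a count in at least 20 cells. The counts were weighted by term frequency and inverse document frequency, reduced by singular value decomposition to 30 components, stripped of component 1, scaled to unit length per cell, and divided by k-means into 4 clusters (20 starts, seed 1). The even-numbered autosomes (102749 regions, 4408718 counts) were held out for all contrasts between clusters. A contrast divides the summed count rate of a region in the cells of 1 cluster by that in all other cells, over the 10069 regions with at least 100 counts. A ratio of 3 was the size rule, and single rates are given as CPM of the even-numbered autosome counts of a cluster. Intervals of sums are exact Poisson intervals, those of ratios are exact conditional intervals and those of shares are exact (Clopper-Pearson) binomial intervals, all at 95%. Correlations of log2 rates used 0.5 added to each sum. For regions raised over all cells, the ratios inside column stretches also used 0.5 added to the count of each cluster. Co-accessibility is the Pearson correlation over cells of binarised counts scaled by depth.

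Regions were named by a rule of size: for each cluster, the 5 even-numbered autosome regions with the highest ratio among those with at least 100 counts in all cells and 40 in the cluster, and the 5 autosomal regions detected in the most cells. The grouping, these thresholds, the naming rule and all but the column-wise alternatives were fixed before the data were examined. The comparisons of cluster pairs, width classes and column stretches, the division of cluster 1 and the shares among neighbouring regions were added afterwards. No doublet caller was run. With 20 nuclei per well and 61 adaptor wells loaded evenly, 27% of nuclei would share well and adaptor barcode with another nucleus. That other nucleus then comes from the same input. Results were recomputed without the 5% of cells with the highest totals, which cannot remove shared barcodes at that rate. Other alternatives were the number of clusters and components, k-means seeds and Leiden clustering (15 neighbours, resolution 1). Region and count minimums, binarised counts, leaving out the 25% of cells with the lowest totals, thinning, and the column stretches apart were also used.

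The grouping and the contrast were tested on simulated counts drawn from the real region means and cell totals. To part the groups, 2000 odd-numbered autosome regions were each raised 3 times in 1 simulated group. The simulated groups were recovered with an adjusted Rand index of 0.949. Among 10183 held-out regions, 100 raised 4 times and 100 raised 6 times were all found at a ratio of 3 or more (100.0% of each). Of the unchanged regions 0.000% reached it. Held-out regions raised by less, and groups that differ by background, were not simulated. In separate draws of paired Poisson counts, which did not use the real means or totals, 96.5% of ratios lay inside their intervals. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.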

Results

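iDNase-seq was applied to human white blood cells to map DNase I hypersensitive regions, the stretches of chromatin open to the nuclease, in single cells. All 480 libraries carried the same label, white blood cells, and formed 1 group. Per the labels' protocols, the crosslinked nuclei came from 4 inputs, T cells, B cells, NK cells and monocytes, each of which received adaptor barcodes in its own wells before pooling. The adaptor wells were split as 15, 15, 15 and 16, so the monocyte input held 26.2% of them and each other input 24.6%. The cells of all libraries shared 1 matrix with unnamed columns, and the matrix was treated as 1 sample without replicates. Intervals given below are exact 95% intervals, binomial for shares and Poisson for sums of counts, and cover counting error only.

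The matrix held 4489 cells and 218042 regions, with 9533608 counts in all. A cell had a median of 1588 counts (quartiles 1153 and 2419), and single cells ranged from 743 to 36067. The median number of regions detected in a cell was 1551. Only 0.932% of the matrix entries were above 0, and 95.86% of those were a single count, so most regions were either seen once or not seen in a given cell. No count at all was found for 620 regions. The totals per library were not analysed here because no column was tied to a library.

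Few hypersensitive regions were detected broadly across cells, and the broad ones were wide. Among the 211887 autosomal regions, 844 had a count in at least 10% of cells (0.398%, 0.372 to 0.426), with a median width of 8600 bases against 800 bases over all autosomal regions. Without the 5% of cells with the highest totals the share was 0.264%. The most widely detected region lay on chromosome 19 (1176501 to 1248300, hg18, 71800 bases) and had a count in 1518 cells (33.82%, 32.43 to 35.22). A pair of chromosome 17 regions followed, at 7676301 to 7707700 with 31.08% of cells (29.72 to 32.45) and at 53753901 to 53778500 with 29.27% (27.94 to 30.63). Regions on chromosome 11 (64938901 to 64957700) and chromosome 2 (196722501 to 196752500) were detected in 27.58% (26.27 to 28.91) and 26.53% (25.24 to 27.85) of cells.

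Wider regions collected more counts, and regions of 2000 to 8000 bases were also the densest. Across autosomal regions, width and total count had a Spearman correlation of 0.828, and width and count per base one of 0.307; regions are not independent replicates. Regions under 500 bases had 23.39 counts per kb over all cells, those of 2000 to 4000 bases 44.61, those of 4000 to 8000 bases 43.88 and those of 8000 bases or more 36.52. The 5965 regions detected in at least 5% of cells made up 2.815% of the autosomal regions and 13.75% of their summed width, and held 23.67% of the autosomal counts.

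The cells were divided into 4 clusters, and separate chromosomes gave similar divisions. Clusters were made from the odd-numbered autosomes alone, with 4 clusters set because the labels name 4 inputs. Cluster 1 held 1346 cells (29.98%, 28.65 to 31.35), cluster 2 held 1258 (28.02%, 26.71 to 29.36), cluster 3 held 990 (22.05%, 20.85 to 23.3) and cluster 4 held 895 (19.94%, 18.78 to 21.14). Clusters made independently from the even-numbered autosomes placed 4245 cells in the matching cluster (94.56%, 93.86 to 95.21). Cluster 4 was matched for 98.88% of its cells, cluster 1 for 97.03%, cluster 2 for 92.61% and cluster 3 for 89.8%. The adjusted Rand index between both sets of clusters, which is 1 for identical groupings, was 0.862, against 0.0032 when counts were dealt to cells by depth alone. With 3 clusters the index was 0.926 and the largest cluster held 49.41% of the cells. Most mismatches lay between clusters 2 and 3: 69 cells of cluster 2 were placed in cluster 3 by the even-numbered autosomes, and 80 cells of cluster 3 in cluster 2. Median counts per cell were 1578.5, 1805.5, 1363 and 1627 in clusters 1 to 4. Without a gene annotation of the hg18 build, the clusters stayed numbered and were not assigned to the inputs.

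**Figure D1:**
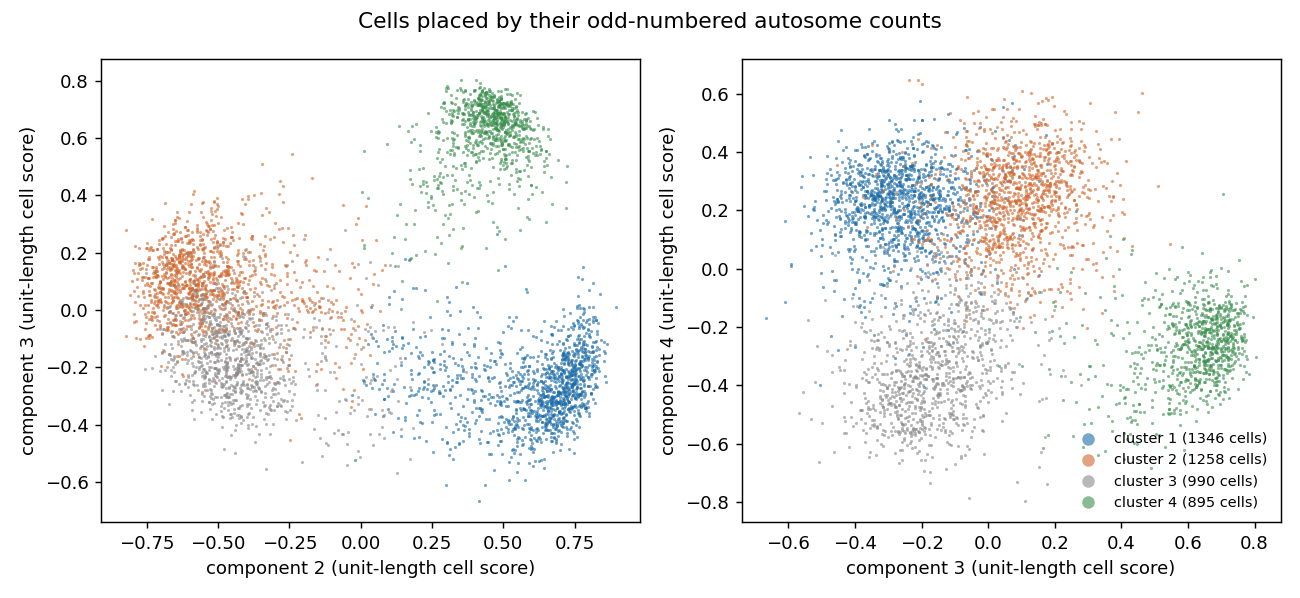
Cells placed by components 2, 3 and 4 of their odd-numbered autosome counts, each point being 1 cell coloured by its cluster and the axes being unit-length cell scores without a unit. On components 2 and 3, most cells of clusters 1 (1346 cells) and 4 (895 cells) lie away from the others, clusters 2 (1258 cells) and 3 (990 cells) adjoin, and scattered cells lie between clusters.

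Clusters 1, 2 and 4 each had many regions with a count rate at least 3 times that of the other cells, and cluster 3 had 8. These values were measured on the even-numbered autosomes, which had no part in making the clusters, as counts in a region per count in all even-numbered autosome regions. Of 10069 regions with at least 100 counts, 534 reached a ratio of 3 in 1 cluster (5.303%, 4.874 to 5.759), and none did in 100 simulations with equal rates in all clusters. The share depended on the count minimum, at 9.465% with at least 50 counts and 1.661% with at least 200. The regions raised in cluster 4 were 1.947% of those compared, those raised in cluster 1 were 1.659%, those raised in cluster 2 were 1.619% and those raised in cluster 3 were 0.079%. A further 4739 regions (47.07%) stayed under 1.5 times in every cluster. With cells thinned to 400 held-out counts, which left out 24, 38, 92 and 16 shallower cells of clusters 1 to 4, 2446 regions kept 100 counts and 1.267% of them reached a ratio of 3, against 0.940% of the same regions before thinning.

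The cluster 4 regions had the highest ratios. The region on chromosome 10 at 49548901 to 49551700 (hg18, as for all positions here) held 74 counts in cluster 4 (58.1 to 92.9) and 32 in the other cells (21.9 to 45.2), a rate ratio of 10.02 (6.53 to 15.68). Chromosome 14 at 63770201 to 63773500 had 122.1 CPM in cluster 4 and 12.3 CPM in the other cells, a ratio of 9.94 (6.91 to 14.51). On chromosome 6 at 88907401 to 88909400 the ratio was 9.87 (6.59 to 15.04). A pair of chromosome 12 regions, at 131120501 to 131122900 and at 106648501 to 106650800, had ratios of 9.64 (6.23 to 15.24) and 9.08 (6.22 to 13.44). In all 5 regions the rates in clusters 1, 2 and 3 lay between 3.9 and 16.9 CPM, against 83.4 to 122.1 in cluster 4.

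In cluster 1 the leading region lay on chromosome 14 at 54872401 to 54874900, with 86 counts (68.8 to 106.2) against 27 in the other cells (17.8 to 39.3), a ratio of 7.88 (5.06 to 12.64). The region on chromosome 20 at 48435401 to 48437600 followed with a ratio of 7.52 (4.73 to 12.34), from 76 counts in cluster 1 and 2 in cluster 4. Another chromosome 14 region, at 106033401 to 106035100, had a ratio of 6.81 (4.49 to 10.54), with 88 counts in cluster 1 and 21, 6 and 5 in clusters 2, 3 and 4. Chromosome 10 at 72031401 to 72034500 and chromosome 12 at 51245901 to 51248500 had ratios of 5.88 (4.16 to 8.42) and 5.86 (4.12 to 8.47).

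The cluster 2 regions were narrower, with a median width of 1600 bases for those at 3 times or more, against 3000 in clusters 1 and 4. The leading one lay on chromosome 2 at 112144901 to 112146100, with 76 counts in cluster 2 (59.9 to 95.1) and 27 in the other cells, a ratio of 5.89 (3.75 to 9.50). A chromosome 6 region at 109268901 to 109270100 had a ratio of 5.75 (3.80 to 8.91), and another at 162522001 to 162523400 one of 5.04 (3.34 to 7.76). Chromosome 8 at 98007601 to 98009100 and chromosome 14 at 89623301 to 89624100 had ratios of 5.11 (3.43 to 7.76) and 5.09 (3.28 to 8.07). Cluster 3 had the next highest rate in all 5 regions: on chromosome 2 it was 21.4 CPM, against 53.3 in cluster 2, 4.8 in cluster 4 and 3.2 in cluster 1.

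Cluster 3 differed from the other cells mainly in wide regions and by smaller ratios. Its 8 regions had a median width of 9450 bases. The highest ratio, on chromosome 22 at 39130101 to 39136700, was 3.68 (2.45 to 5.50), from 50 counts in cluster 3 (37.1 to 65.9) and 54 in the other cells (40.6 to 70.5). Chromosome 16 at 2071301 to 2084200 had a ratio of 3.32 (2.32 to 4.73) and chromosome 14 at 102668201 to 102676100 one of 3.14 (2.18 to 4.51). Chromosome 12 at 51737301 to 51743600 and a second chromosome 22 region at 48953801 to 48962300 had ratios of 3.08 (2.04 to 4.63) and 3.04 (2.15 to 4.28). The counts of cluster 3 were spread more evenly: the densest 10% of held-out regions took 27.66% of them (27.57 to 27.75), against 35.35%, 36.57% and 35.67% in clusters 1, 2 and 4. The 20 named regions were picked by their ratio on the same counts, which favours high values, and the lower bounds of the cluster 3 ratios lay under 3.

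**Figure D2:**
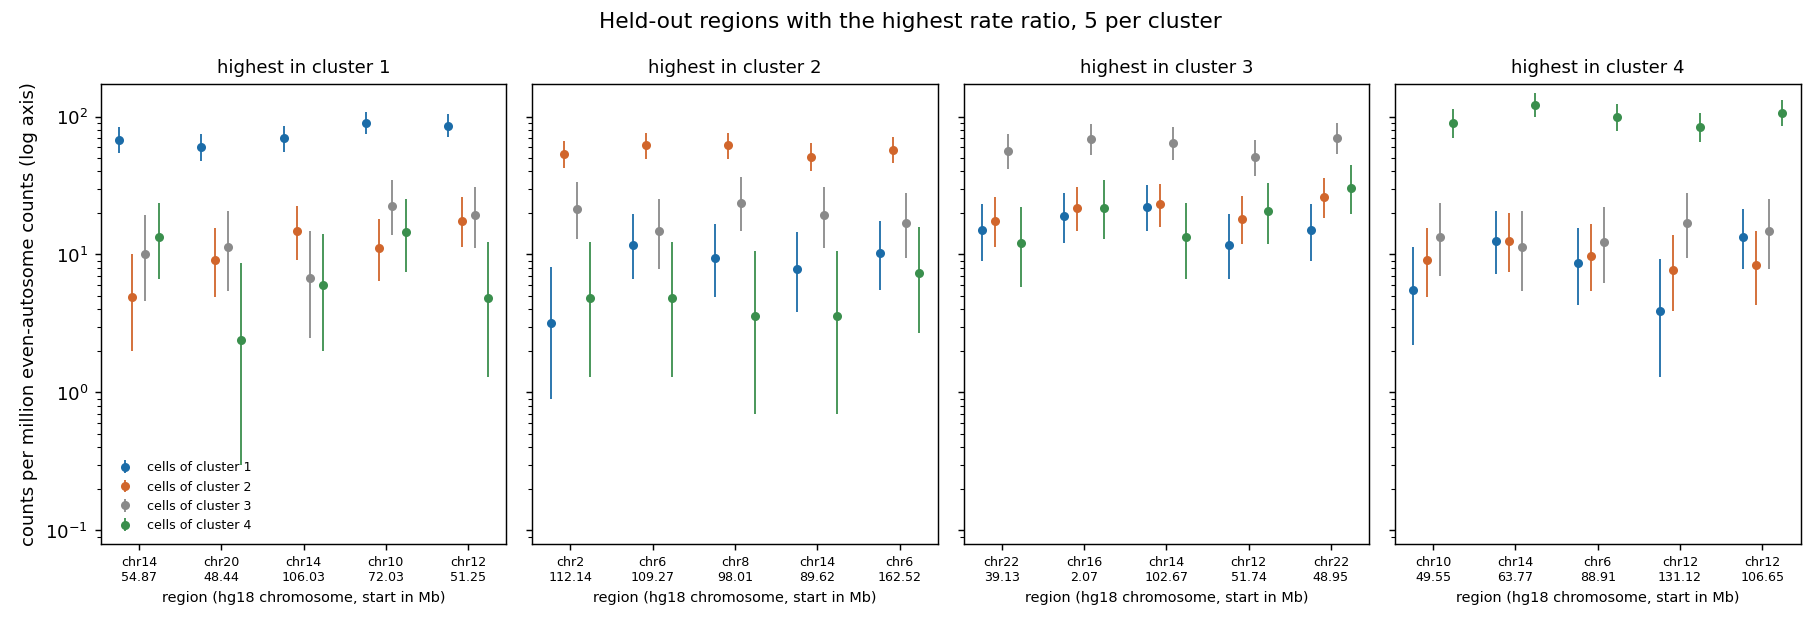
Count rate in CPM of the even-numbered autosome counts (log axis) in the 5 held-out regions with the highest rate ratio in each cluster, one panel per cluster; points are the rates in the cells of clusters 1 to 4 and bars are exact 95% Poisson intervals. In the cluster 4 panel its rates lie between 83.4 and 122.1 and those of the other clusters at 16.9 or less, while in the cluster 3 panel the rates lie closer together.

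Clusters 2 and 3 had the most similar profiles, both by correlation and by the share of regions that differed at least 3 times; clusters 2 and 4 had the lowest correlation, and clusters 1 and 2 the highest share. Over the 10069 held-out regions, the Pearson correlation of log2 rates was 0.734 between clusters 2 and 3, 0.628 between clusters 1 and 4, 0.519 between clusters 1 and 3, 0.467 between clusters 1 and 2, 0.464 between clusters 3 and 4 and 0.443 between clusters 2 and 4. Randomly divided cells of 1 cluster gave 0.891, 0.862, 0.742 and 0.839 for clusters 1 to 4. Compared pair by pair, 0.13% of 3927 regions differed at least 3 times in rate between clusters 2 and 3, 3 being higher in cluster 2 and 2 in cluster 3. The share was 6.7% of 5418 regions between clusters 1 and 2, 6.24% of 4119 between clusters 2 and 4, 4.28% of 4043 between clusters 1 and 4, 4.05% of 2121 between clusters 3 and 4 and 3.3% of 3731 between clusters 1 and 3. Each pair kept the regions with at least 100 counts in its 2 clusters. The shares are therefore over different regions, and their order may partly reflect the counts each pair held. Regions are not independent replicates, and the divided cells held fewer counts than whole clusters, so their correlations are no upper limit.

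Cluster shares differed along the column order of the matrix, which is not explained in the sources used here. Columns 1 to 500 were 98.6% cluster 4, columns 1001 to 1500 were 72.4% cluster 3 and 27.4% cluster 2, and columns 2001 to 2500 were 90% cluster 1. From column 2501 on, the clusters were mixed: columns 4001 to 4489 were 39.5% cluster 1, 47.9% cluster 2, 3.1% cluster 3 and 9.6% cluster 4. Depth changed along the order too, with median counts per cell of 1284 in columns 2001 to 2500 and 2806 in columns 2501 to 3000. Inside columns 2501 to 4489 alone, the rate was higher in the same cluster for all regions of clusters 1, 2 and 3 and for 99% of those of cluster 4. Inside columns 1 to 2500 this held for all 534. For the leading regions of clusters 1, 2, 3 and 4 the ratios inside columns 2501 to 4489 were 10.09, 7.13, 3.05 and 9.80, and inside columns 1 to 2500 they were 7.15, 5.62, 4.20 and 7.32. All 20 named regions kept a ratio above 1 in both stretches. The lowest in columns 2501 to 4489 were those of the cluster 3 regions on chromosome 14 (1.32, from 4 counts in cluster 3) and chromosome 12 (1.74, from 3 counts), and in columns 1 to 2500 those of the cluster 3 region on chromosome 16 (2.45) and the cluster 2 region on chromosome 8 (2.47). These cells are part of the overall values, and cluster 3 had 95 cells in the mixed columns. With the fewer regions that kept 100 counts in each stretch, 3.628% of 3363 (3.022 to 4.316) reached a ratio of 3 in columns 1 to 2500 and 2.784% of 4311 (2.313 to 3.319) in columns 2501 to 4489; over all cells the same regions gave 2.319% and 2.064%.

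**Figure D3:**
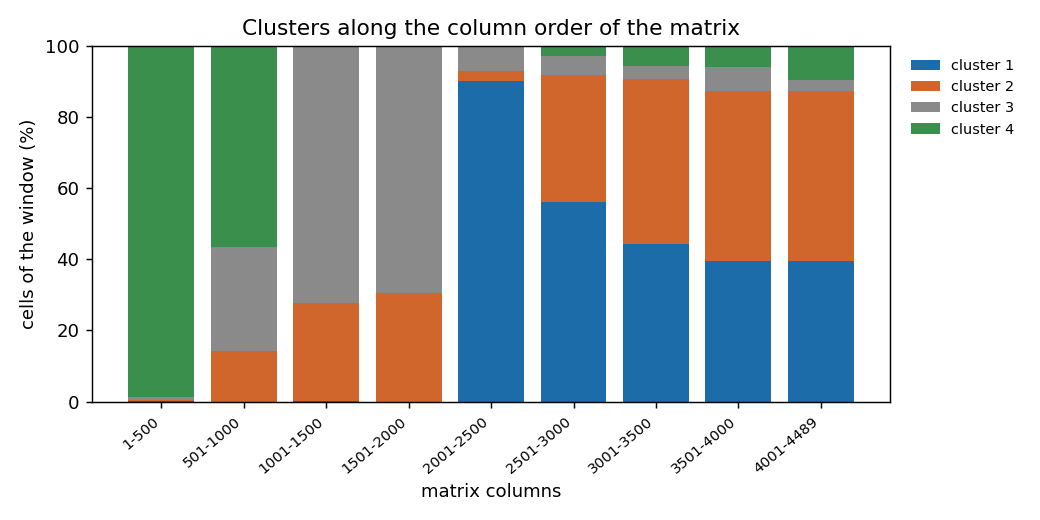
Share of cells (%) in clusters 1 to 4 in consecutive windows of 500 matrix columns, the last holding the remaining columns; the bars stack to 100%. Cluster 4 makes up 98.6% of the first window and cluster 1 90% of columns 2001 to 2500, while later windows are mainly clusters 1 and 2.

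Correlations between neighbouring regions over cells were close to 0, and the sign of their median under 5 kb depended on the detection minimum. Over 2697 even-numbered autosome regions detected in at least 5% of cells, the median correlation over cells was 0.0109 for 13 pairs under 5 kb apart (0.006 to 0.0185, resampling the pairs) and 0.0031 at 5 to 20 kb (0.0009 to 0.0047). It was 0.0027 at 20 to 100 kb, 0.0014 at 100 kb to 1 Mb and 0.0 between chromosomes. Within clusters 1, 2, 3 and 4, each with its own regions detected in at least 5% of its cells, the medians under 5 kb were -0.0018, -0.0001, -0.0126 and -0.0024 over 24, 58, 5 and 38 pairs. Their intervals all included the cluster's median between chromosomes. At 100 kb to 1 Mb the medians were -0.0012 in cluster 1 (-0.0021 to -0.0006) and -0.004 in cluster 2 (-0.0045 to -0.0034), above those between chromosomes, -0.0028 (-0.0034 to -0.0023) and -0.0063 (-0.0068 to -0.0057). In cluster 3 (-0.0056, -0.0074 to -0.0038) and cluster 4 (-0.0042, -0.005 to -0.0032) the intervals overlapped those between chromosomes, -0.006 (-0.0067 to -0.0053) and -0.0048 (-0.0054 to -0.0042). Pairs share regions, so these intervals are too narrow. Sparse counts can pull such correlations toward 0. No linked regions were simulated, so values near 0 do not show that neighbouring regions open independently. With regions detected in at least 2% of cells the pooled median under 5 kb was -0.000309 over 761 pairs, and without the 5% of cells with the highest totals it was 0.00547.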

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

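The column-stretch alternatives were chosen after the data were seen; the others were planned. The largest cluster share stayed within its interval under 15 of 19 alternatives, and was 49.41%, 27.98% and 25.06% with 3, 5 and 6 clusters and 27.27% with Leiden clustering. Among the 15 were reruns with k-means seeds 2 to 6, which all gave 29.98%. The share does not show which cells the largest cluster held. The Rand index between odd-numbered and even-numbered autosomes was 0.9256, 0.808 and 0.8091 with 3, 5 and 6 clusters, 0.7847 with Leiden clustering, 0.8471 with 10 components, 0.7784 with regions in at least 100 cells, 0.8431 without the 5% of cells with the highest totals and 0.8787 without the 25% with the lowest; 4 alternatives kept it in its interval. The share of held-out regions at the set ratio, 5.303%, was 21.08% at a ratio of 2 and 0.576% at 5, 9.465% with at least 50 counts and 1.661% with at least 200, 7.399% with 3 clusters, 4.334% with binarised counts, 4.796% without the highest totals, 1.267% with thinned cells, 3.628% in columns 1 to 2500 and 2.784% in columns 2501 to 4489. The last 3 compared fewer regions, since fewer reached 100 counts. It stayed within its interval under 4 alternatives. Median counts per cell were 1540 without the highest totals, 1551 binarised and 1401 over regions in at least 20 cells. The share of regions detected in at least 10% of cells was 2.815% at 5% of cells, 0.2643% without the highest totals and 0 with at least 2 counts required. The width and count correlation was 0.7347 over regions in at least 20 cells and 0.3072 per base. The co-accessibility median under 5 kb changed sign, to -0.0003094, with regions in at least 2% of cells, and was 0.005471 without the highest totals; at 10% of cells no pair lay under 5 kb. Where the construction of an alternative does not show it, the cause was not tested. Marker regions, promoter shares and the comparison of inputs were not run, nor were their alternatives, for want of an hg18 annotation and of a map from cells to adaptor wells. No paired analysis was possible because the libraries formed 1 group. Depth limits single regions: the median autosomal region held 21 counts over all cells.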

Other observations

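Regions that were open more often in 1 cluster lay near others of the same cluster. Among 2123 held-out regions with a rate at least 2 times that of the other cells, 75.3% of the pairs under 10 kb apart had the same cluster (68.3 to 81.4, exact binomial). The share was 65.1% (61.2 to 68.9) at 10 to 50 kb, 51.1% at 50 to 100 kb, 39.2% at 100 to 500 kb and 33.4% at 0.5 to 1 Mb, against 29.3% from the numbers of such regions per cluster alone. Pairs share regions and are not independent.

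With 5 clusters in place of 4, cluster 1 divided and the other clusters stayed nearly whole. The parts held 700 and 651 cells, with median counts per cell of 1528 and 1618. The region with the highest ratio in one part lay on chromosome 12 at 51245901 to 51248500, the fifth region named for cluster 1, with 99 counts in that part and 12 in the other (ratio 7.62). In the other part it lay on chromosome 4 at 143705501 to 143709600, with 77 counts against 24 (ratio 3.30). Both were picked after their values were seen.

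Of the tests that follow, the mixture test of cluster 3 replaced an earlier form after that form's result was seen, the column stretches were picked after the cluster shares along the columns were seen, and the tests inside windows of 500 columns were chosen after those shares and the overall Rand index were seen. No biological explanation was tested, since the labels give 1 group. Cluster 3 spread its counts more evenly over regions than the other clusters. Shallow cells do not account for it, since among cells of 1000 to 1500 counts the share in the densest 10% of regions was 36.31% in cluster 2 and 27.27% in cluster 3, a gap of 9.043 percentage points. Inside columns 1001 to 2000 the gap was still 7.342 points, so the stretch of matrix columns alone does not account for it. Those columns held 710 of the 990 cluster 3 cells, and cells were sorted by profile, so a part played by the stretch stays open. It also stays open that cluster 3 may be cells like those of cluster 2 with more background cutting. A mixture of the cluster 2 profile and counts in proportion to width was fitted to cluster 3. It was also fitted to cluster 2 cells with 43.44% background added, the amount that matched cluster 3. The mean squared residual of cluster 3 was 1.184 times that of these cluster 2 cells, just under the bound of 1.2 set for it. In that mixture 11 of 2586 dense regions stood at 2 times the fit or more, against at most 5 in simulated mixtures, while cluster 1 had 606.

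Neighbouring columns of the matrix shared a cluster in 61.01% of cases, against 25.68% by chance. Depth along the column order does not account for it, since among cells of 1000 to 1500 counts the excess over chance was 37.86 percentage points. Profiles set by the stretch of columns alone would leave no clusters inside a stretch. In columns 2501 to 4489, where clusters were mixed, odd-numbered and even-numbered autosomes parted cells alike inside every window of 500 columns. The lowest adjusted Rand index there was 0.784, so the stretch alone does not account for those clusters. In columns 1 to 2500 the lowest index was 0.569, but these windows cannot decide the question. Columns 501 to 1000 passed from mainly cluster 4 to clusters 2 and 3, so that window spans a change of stretch. Columns 1001 to 2000 held almost only clusters 2 and 3, which may differ by background. In columns 1 to 2500, 77.44% of cells were in the commonest cluster of their window, and columns 1 to 500 held 7 cells of other clusters. Profiles set by the stretch therefore stay open in columns 1 to 2500. What set the order of the columns is not given in the sources used here and stays open.

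With 6 clusters, the smallest had a median of 2456 counts per cell, against 1555 in the others, and took cells mainly from clusters 1 and 2, with 39 from cluster 3 and 10 from cluster 4. After thinning every cell to at most 1500 counts, the best matching cluster shared 12.7% of its union with it. The rule set beforehand took an overlap this low to mean that depth alone could account for the cluster. The overlap was not measured for the other clusters, so this value cannot show whether depth made the cluster. Over all cells the upper quartile was 2419 counts, yet 7.151% of all cells lay nearest to the cluster. Most cells of such depth therefore lay in other clusters. This comparison was not among the planned tests, and it goes against the outcome of the rule. Depth, alone or in part, stays open. Nuclei of different clusters under 1 barcode pair also stay open. Of 400 simulated pairs of different clusters, 41.25% lay nearest to that cluster, against 14% of pairs from 1 cluster. Each kind of pair was placed anew together with all cells. The 7.151% of all cells was measured without pairs and follows from the size of the cluster, so it is no like comparison. The simulated pairs could join any different clusters, whereas nuclei that share well and adaptor barcode come from the same input. The clusters were not assigned to inputs, so how far the simulation matches real pairs is unknown. Thinning would also weaken a cluster of such pairs.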
